A study of Homo sapiens with 80 samples.

How the data were processed

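Messenger RNA was measured in TH2 cells sorted from the blood of 80 donors, 40 with asthma, 25 with allergic rhinitis and 15 healthy donors without allergy, 1 library per donor. Per the labels' protocols, the cells were sorted into lysis reagent without culture, 5 ng of total RNA was amplified by the Smart-seq2 method with 16 cycles, and libraries were made with Nextera XT. That method copies polyadenylated RNA by PCR, carries no molecular identifiers and does not mark the strand, so floors of 3 counts reflect counting of reads and not of molecules, and reads of overlapping antisense genes cannot be told apart. The values are the raw counts of reads per gene symbol that the authors deposited, counted with HTSeq on the hg19 build, per the submitters' processing notes. The HTSeq version, the aligner, the annotation and the counting mode are not given in the sources used here. The deposited count table holds 19886 gene symbols and no summary rows, and 84 genes had no count in any library. It holds no gene encoded by the mitochondrial genome, so the list of those genes had no measured member. Because the annotation at hand was of another build than hg19, no coordinates are given.

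Groups were taken from the disease group in the labels. The donors are separate people and no replicate number is shared between groups, so no pairing was used. No sequencing batch, date or handling record is in the labels. Libraries were checked for duplicates by a chi-square comparison of counts over 10166 genes in each of 3160 pairs: the lowest chi-square per degree of freedom was 6.96, where sampling noise alone gives about 1, so each library counted once. XIST, TSIX and Y-linked genes, 24 in all, were removed before library sizes and tests, because they follow the sex of donors.

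The main test was edgeR 4.0.16 in R 4.3.3. All 80 libraries entered 1 fit with 3 group means, TMM scaling, the filterByExpr filter by group (smallest count 10), robust dispersion estimates and the quasi-likelihood F test. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. The filter left 11963 genes, and the common biological coefficient of variation was 29.9%. Levels are given as CPM, computed from the deposited counts after TMM scaling, as mean ± SD over libraries. The standard error of a log2 fold change was obtained from the F statistic. The 39 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 38 lists with measured members in each comparison. The share of counts in 14 marker lists of cell types, and the depth measures, were compared by two-sided permutation tests with 100000 resamples in Python 3.11.15 and scipy 1.17.1, adjusted over 42 and 18 comparisons.

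The comparisons, lists and alternatives were fixed before the data were examined, and so was the rule for named genes. For each comparison that rule takes, among genes past the threshold with a mean of at least 5 CPM in one group, the 10 with the largest increase and the 10 with the largest decrease, leaving out HLA, immunoglobulin and T cell receptor variable, KIR and clone-named genes. It adds up to 4 members of each list past the threshold with the smallest p. It also adds a panel of GATA3, IL4, IL5, IL13, PTGDR2, IL17RB, IL1RL1, CCR4, CCR7, TBX21, RORC, FOXP3 and FKBP5, whether or not they passed, and, where fewer than 10 genes pass, the 10 with the smallest p.

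The pipeline was tested on simulated data in which 100 genes were changed 1.5-fold and 100 genes 2-fold, drawn from the means and library sizes of the libraries. Of the 2-fold changes it recovered 85% for asthma against healthy, 85% for rhinitis against healthy and 97% for asthma against rhinitis. Of the 1.5-fold changes it recovered 72%, 58% and 78% in the same order, with 6, 8 and 7 false calls. Each gene was drawn independently, so the false calls do not measure error where genes vary together, as they do in real libraries. Random splits of the real libraries into groups of the same sizes gave up to 23, 328 and 5 genes in the same order.

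Alternatives planned in advance were RLE, upper-quartile and no scaling, no filter and a stricter filter (5 CPM in 15 libraries), non-robust estimates and a fit of only the 2 groups compared. Covariates tried were log2 library size, the number of detected genes and 2 surrogate variables (sva 3.50.0). Other choices were leaving out 4 libraries more than 3 MAD from the median in depth or detected genes, a minimum fold of 1.5, DESeq2 1.42.0 and limma voom with sample quality weights. Camera was repeated with an estimated correlation and set beside fry, which tests whether a list's genes move, on balance, one way. Added after seeing the data were leaving out each library in turn, leaving out 2 libraries more than 5 MAD from the median on the first 4 principal components, an offset for each library's GC and length trend (known for 11439 of 11963 genes), and each library's immediate early score as a covariate. Comparisons that share the healthy libraries were set beside 20 simulations with no group effect and 20 splits of the healthy libraries into 8 and 7. These simulations also drew each gene independently.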

Results

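The study profiled messenger RNA from circulating TH2 cells, the CD4 T cells that drive allergic inflammation. The cells were sorted from blood as CCR4-positive central memory helper cells without CD25, and were lysed without culture. The 80 libraries came from 40 donors with asthma, 25 donors with allergic rhinitis and 15 healthy donors without allergy. Each library held between 2226923 and 9837249 counted reads. Mean totals were 6093150 ± 1380170 reads in asthma (SD, n = 40), 5562880 ± 1319590 in rhinitis (SD, n = 25) and 5112940 ± 1058390 in healthy donors (SD, n = 15). The asthma libraries were deeper on average than the healthy ones (two-sided permutation test p = 0.015, adjusted p = 0.135 over 18 comparisons). The rhinitis libraries had 235 more detected genes than the healthy ones (p = 0.0104, adjusted p = 0.135 by the same test), and 96.6 more when detection required 10 counts (p = 0.329). At the shallowest library 3 counts correspond to 1.35 CPM (counts scaled to a common library total), and at the deepest to 0.30 CPM. Of 19886 genes in the deposited table, 11963 were abundant enough to test.

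Genes of the sort and of the TH2 lineage were expressed in all groups, which does not measure how pure the sorted cells were. GATA3, the TH2 lineage transcription factor, stood at 189 ± 38.5 CPM in asthma (SD, n = 40), 210 ± 71.3 CPM in rhinitis (SD, n = 25) and 215 ± 24.9 CPM in healthy donors (SD, n = 15). CCR4, used in the gate, stood at 144 ± 44.6, 155 ± 76.1 and 195 ± 62.3 CPM, and CCR7, also used in the gate, at 469 ± 133, 431 ± 104 and 530 ± 125 CPM in the same order. IL4, IL5 and IL13, the effector cytokine genes of TH2 cells, and IL1RL1, the IL-33 receptor gene, averaged under 0.35 CPM in each group and were too low to test, so no difference in them was detectable at this depth. TBX21, RORC and FOXP3, which mark other helper lineages, did not pass the test in any comparison.

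The first comparison asked how TH2 cells of asthmatic donors differ from those of healthy donors. Genes of the early response to T cell stimulation were lower in asthma. NR4A1, an orphan nuclear receptor induced by T cell receptor signalling, was 7.20-fold lower at 1.53 ± 1.75 CPM against 11.2 ± 11 CPM, and lay below the healthy median in 40 of 40 asthma libraries. FOS, a component of the AP-1 transcription factor, was 3.15-fold lower at 303 ± 208 against 955 ± 1196 CPM. Several metallothionein genes, which encode small zinc-binding proteins, were higher, as were PTGDR2 and IL17RB, which encode the prostaglandin D2 receptor CRTH2 and a subunit of the IL-25 receptor. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 457 of 11963 genes passed adjusted p 0.05, of which 155 were higher and 302 lower. With a fold of at least 1.5 in addition, 37 genes were higher and 171 lower. Of the 457 genes 66.1% were lower, against 56.2% of 482 genes without scaling factors and 52.5% of 528 genes with 2 surrogate variables. The count was 697 with only these 2 groups in the fit, 1735 with limma voom, and 20 with each library's immediate early score as a covariate, of which 14 were among the 457.

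Of the 26 measured genes of the immediate early and T cell activation list, 14 fell, 1 rose and the remainder did not pass (21 fell and 1 rose when adjusted over the list alone). On the log2 scale NR4A3 changed by −2.13 (SE 0.47) and NR4A2 by −1.68 (SE 0.40). ZFP36, which promotes the decay of cytokine mRNA, fell by 1.40 (SE 0.21), as did DUSP5 (−1.46, SE 0.22) and DUSP1 (−1.01, SE 0.16), phosphatases that switch off MAP kinases. The member that rose was MYC, a growth-promoting transcription factor gene that was named here only after its value was seen. The list was called lower by camera (adjusted p = 3.8e-17), and also with an estimated correlation (adjusted p = 0.0203). Each library's immediate early score, the mean scaled log2 CPM of these genes, averaged −0.245 ± 0.418 in asthma and 0.569 ± 0.673 in healthy donors (SD). The groups overlapped: the score lay inside the healthy range in 39 of 40 asthma libraries and below it in 1. Of the 17 genes of the NF-kB response list, 10 fell and none rose (14 fell when adjusted over the list alone). NFKBIA, which encodes an inhibitor of NF-kB, was 1.90-fold lower at 370 ± 122 against 704 ± 283 CPM, and TNFAIP3, an inhibitor of the same pathway, was 2.19-fold lower. CD83 (−1.12, SE 0.18) and BCL3 (−1.11, SE 0.25) also fell. This list was called lower with the preset correlation (camera adjusted p = 2.5e-13) and with an estimated correlation (adjusted p = 0.0139).

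The glucocorticoid response list moved in both directions, with 9 of 20 genes lower and 3 higher (12 lower and 3 higher when adjusted over the list alone). The 3 that rose were the metallothioneins MT1E, MT1X and MT2A. Those that fell included SGK1 (−1.39, SE 0.27), TSC22D3 (−0.67, SE 0.14), ERRFI1 (−1.61, SE 0.35) and DUSP1, which the immediate early list also holds. FKBP5, a direct glucocorticoid target, was not past the threshold at 265 ± 93.8 against 359 ± 192 CPM (adjusted p = 0.0892 by edgeR's quasi-likelihood test). The list was called lower by camera (adjusted p = 9.4e-07), a call lost with an estimated correlation (adjusted p = 0.120).

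Of the genes that passed and that the naming rule ranks (at least 5 CPM in one group, some families left out), metallothioneins and SLC30A1 had the largest increases in edgeR. These metallothioneins were MT1G, MT1E, MT1X and MT2A, and SLC30A1 is a zinc exporter gene. MT1X stood at 135 ± 288 CPM in asthma (SD, n = 40) against 22.5 ± 6.33 CPM in healthy donors (SD, n = 15), and exceeded the healthy median in 33 of 40 libraries. MT2A stood at 251 ± 482 against 63.1 ± 26.2 CPM, MT1E at 51.3 ± 112 against 6.16 ± 2.99 CPM and MT1F at 20.3 ± 16.8 against 11.3 ± 4.80 CPM. MT1G was near the floor in healthy donors, with 9 counts over the 15 libraries, and averaged 11.4 ± 30.7 CPM in asthma. SLC30A1, which encodes a zinc exporter, was 3.51-fold higher at 18.9 ± 22.5 against 5.36 ± 2.22 CPM. The metallothionein genes are close paralogs whose reads the counting can split, so their individual values are uncertain. The spread in asthma was wide, and with limma voom and sample quality weights the calls of all 5 metallothioneins and SLC30A1 ended, with log2 fold changes of 1.37 for MT1X (adjusted p = 0.0806) and 1.35 for SLC30A1 (adjusted p = 0.0751).

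PTGDR2 was 3.41-fold higher in asthma, at 6.70 ± 5.50 CPM (SD, n = 40) against 1.94 ± 1.95 CPM (SD, n = 15), with an adjusted p of 0.0051 in edgeR. IL17RB was 3.38-fold higher, at 10.3 ± 6.60 against 3.06 ± 1.55 CPM, with an adjusted p of 4.4e-04 in edgeR. Each lay above the healthy median in 37 of 40 asthma libraries. PTGDR, which encodes the other prostaglandin D2 receptor, rose by 1.31 (SE 0.37) on the log2 scale, a call that ended with the number of detected genes as a covariate (adjusted p = 0.0564) and with 2 surrogate variables (adjusted p = 0.129). In the prostaglandin and leukotriene list 2 of 16 genes rose and 1 fell, the latter being PTGER4, a prostaglandin E2 receptor gene, which fell by 0.97 (SE 0.17). The Th2 lineage list had 2 of 9 measured genes higher, and the pathogenic effector Th2 list 2 of 12 higher and NAMPT lower, and in both lists the genes that rose were PTGDR2 and IL17RB. When adjusted over the list alone, 3 genes rose and 2 fell in the Th2 lineage list, and 2 rose and 1 fell in the pathogenic effector list. Neither list was called as a whole (camera adjusted p = 0.737 and 0.767), and their medians (−0.04 and −0.01) and means (0.35 and 0.28) differed in sign. CHRNB1, a nicotinic acetylcholine receptor subunit gene, rose by 0.93 (SE 0.15) and exceeded the healthy median in 40 of 40 libraries, and EMR1 rose by 0.88 (SE 0.24).

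Further genes with large decreases were CDKN1A, a cell cycle inhibitor (5.38-fold lower), RGS16, a regulator of G protein signalling (4.26-fold lower), TRAF4 (3.15-fold lower), SIK1, a salt-inducible kinase gene (2.89-fold lower), and LYPD3 (2.84-fold lower). In the cholesterol synthesis list 4 of 17 genes fell, among them HMGCR, the rate-limiting enzyme of the pathway (−0.52, SE 0.14), and HMGCS1 (−0.57, SE 0.14). In the circadian clock list BHLHE40 and PER1, 2 of 15 genes, fell (−1.17, SE 0.21 and −1.16, SE 0.27). The cell cycle list had RRM2 and TK1 lower among 19 genes, the pro-apoptotic list had BCL2L11, BIK and CASP9 lower among 21, and the survival list had PIM3 and BIRC2 lower among 19. PDCD1 and CXCR5 were lower in the follicular helper list (2 of 11), and LRRC32 in the regulatory T cell list (1 of 13). HIST1H1C and HIST1H1E were lower among 11 histone genes, a list meant to follow how polyadenylated RNA was captured, though whether it does so here was not tested. None of the 15 interferon gamma response genes passed alone (3 rose and 1 fell when adjusted over the list alone), and the list was called higher. The camera calls of these 9 lists (adjusted p from 0.0021 to 0.0203) were all lost with an estimated correlation (adjusted p from 0.0812 to 0.254).

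The other 26 lists with measured genes were not called in asthma (camera adjusted p from 0.0697 to 1.00). They covered Th17 and Th22, Th1 and cytotoxic, naive and central memory, CD8 T and NK, B cell, monocyte, neutrophil, eosinophil and basophil, dendritic, platelet and erythroid markers. Only 4 B cell, 2 neutrophil, 1 eosinophil and basophil, 2 dendritic, 3 platelet and 1 erythroid genes were tested, so a missing call says little there. The 1 eosinophil and basophil gene was higher by 1.03 on the log2 scale without passing, and fry called that list (adjusted p = 0.0345). The 26 lists also covered the Th2, pathogenic Th2, type I interferon, JAK-STAT, oxidative phosphorylation, glycolysis, fatty acid, heat shock, unfolded protein, ribosomal protein, chemokine receptor, prostaglandin, asthma locus, housekeeping and gate marker lists. Single members passed in some of them: PFKFB3, SLC2A3 and SLC16A3 fell and HK1 rose in glycolysis, and CCL20 fell in the Th17 and Th22 list. CXCR4, CCR9 and CXCR5 fell among the chemokine receptors, and KLF2, ACSL3, DNAJB1, SOCS3 and ZBTB10 fell in the naive, fatty acid, heat shock, JAK-STAT and asthma locus lists. The calls of HK1, NAMPT, CASP9, CCR9, CXCR4, EMR1, SLC16A3, HIST1H1C and HIST1H1E each ended in at least 1 alternative scaling, filter, covariate or choice of libraries. With each library's immediate early score as a covariate, 1 of the 62 named genes past the threshold in asthma, MT1G, kept its call.

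The share of counts in cell type marker genes moved with asthma in 4 of 14 lists, 3 of other cell types and 1 of the Th2 lineage itself. B cell markers took 50.7 ± 12.3 CPM in asthma and 40.3 ± 7.44 CPM in healthy donors (adjusted p = 0.0424, two-sided permutation test of log2 shares). Th17 and Th22 markers were lower by 0.26 on the log2 scale (adjusted p = 0.0499), follicular helper markers by 0.25 (adjusted p = 0.0424) and Th2 lineage genes by 0.15 (adjusted p = 0.0424) in the same test. All 4 calls ended without the 4 libraries that stood apart in depth or detected genes (adjusted p from 0.0578 to 0.118), although the log2 differences were then 0.34 for B cell, −0.22 for Th17 and Th22, −0.26 for follicular helper and −0.14 for Th2 lineage genes. Monocyte markers took 124 ± 73.6 CPM in asthma and 111 ± 58.7 CPM in healthy donors (adjusted p = 0.931 in that test). Eosinophil and basophil markers, of cells that the CD3 gate would remove, took a mean of 4.23 CPM in asthma and 2.84 CPM in healthy donors (medians 4.01 and 2.67 CPM). They were higher by 0.62 on the log2 scale in asthma (p = 0.0305, adjusted p = 0.160 in that test), by 0.56 in rhinitis (adjusted p = 0.304) and by 0.76 in asthma without those 4 libraries (adjusted p = 0.0578). The mean of the whole list rose by 1.38 CPM, where PTGDR2 alone, which these cells also express, went from 1.94 to 6.70 CPM.

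**Figure D1:**
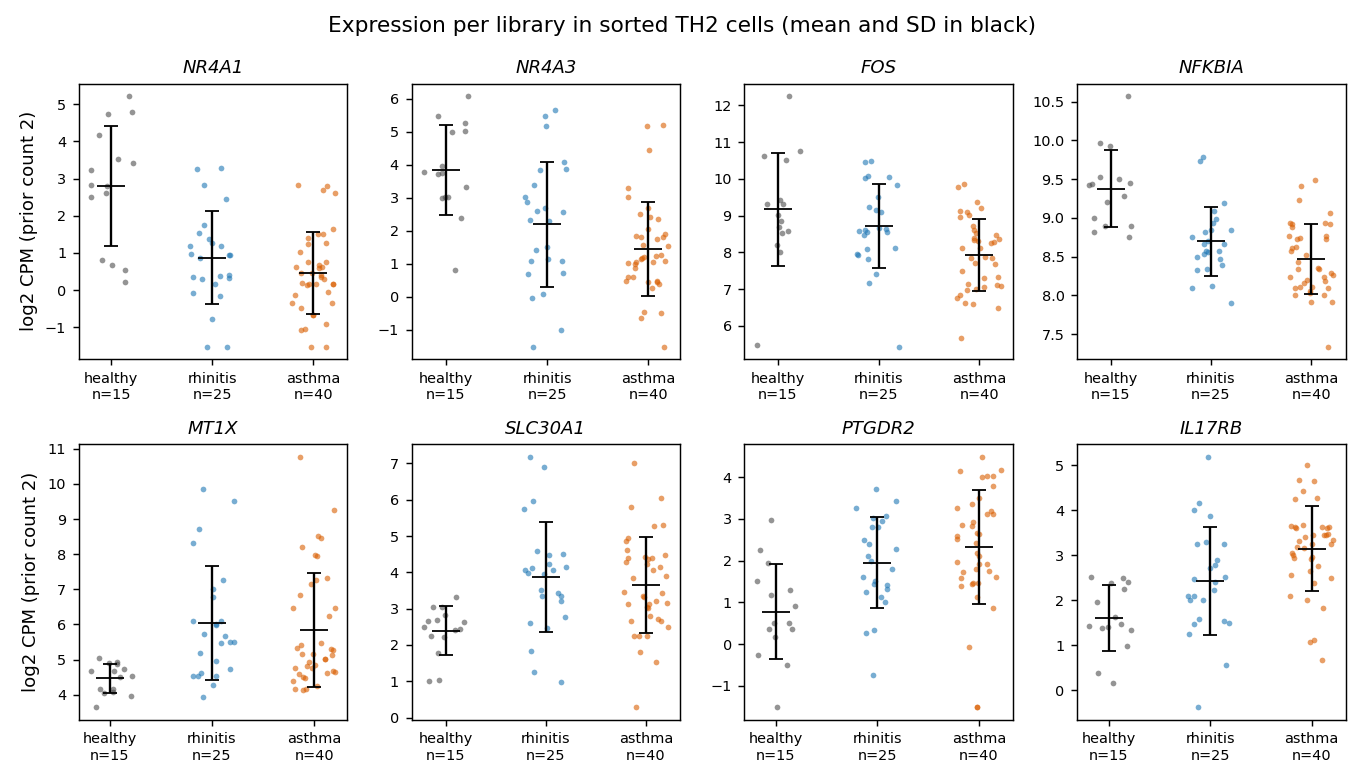
Expression of 8 genes in each library (log2 CPM with a prior count of 2, vertical axes) by donor group (horizontal axes: 15 healthy, 25 rhinitis and 40 asthma libraries), with each point a library and black marks the mean and SD. NR4A1, NR4A3, FOS and NFKBIA were lower, and MT1X, SLC30A1, PTGDR2 and IL17RB higher, in asthma than in healthy donors, and the spread of MT1X was wider in both allergic groups than in healthy donors.

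The second comparison asked the same of allergic rhinitis. NR4A1 was again lower, 4.86-fold, at 2.28 ± 2.60 CPM (SD, n = 25) against 11.2 ± 11 CPM (SD, n = 15). RGS16 was 3.83-fold and DUSP5 2.63-fold lower, and each lay below the healthy median in 24 of 25 libraries. The metallothioneins MT1G, MT1E, MT1X and MT2A were higher, with MT1X at 140 ± 229 against 22.5 ± 6.33 CPM and MT2A at 278 ± 408 against 63.1 ± 26.2 CPM, and SLC30A1 was 4.71-fold higher at 25.4 ± 35.1 against 5.36 ± 2.22 CPM. By edgeR's quasi-likelihood test 197 of 11963 genes passed adjusted p 0.05, of which 87 were higher and 110 lower. With a fold of at least 1.5 in addition, 26 genes were higher and 68 lower.

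In the immediate early and T cell activation list 5 of 26 genes fell and 1 rose in rhinitis (9 fell and 1 rose when adjusted over the list alone). The gene that rose was MYC, by 0.79 (SE 0.17), and CD40LG, the CD40 ligand gene, fell by 0.36 (SE 0.08). In the NF-kB response list 5 of 17 fell (6 when adjusted over the list alone), including NFKBIA (−0.70, SE 0.15), CD83 (−0.83, SE 0.20), BCL3 (−1.10, SE 0.28) and TNFAIP3 (−0.76, SE 0.20). Both lists were called lower by camera (adjusted p = 4.0e-08 for each), and both calls were lost with an estimated correlation (adjusted p = 0.202 and 0.186). The immediate early score averaged 0.0505 ± 0.575 in rhinitis (SD), inside the healthy range in 24 of 25 libraries and below it in 1. The glucocorticoid list again had MT1E, MT1X and MT2A higher and 2 of 20 genes lower, DUSP1 (−0.81, SE 0.18) and TSC22D3 (−0.58, SE 0.15). Its median was −0.39 and its mean 0.04, and it was called lower (camera adjusted p = 0.0034), a call lost with an estimated correlation (adjusted p = 0.394). As in asthma, the calls of MT1G, MT1E, MT1X, MT2A and SLC30A1 ended with limma voom and sample quality weights (log2 fold change 1.63 and adjusted p = 0.0762 for MT1X, adjusted p = 0.0974 for SLC30A1).

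IL17RB rose 2.35-fold in rhinitis, to 7.20 ± 7.48 against 3.06 ± 1.55 CPM, close to the threshold (edgeR adjusted p = 0.0484). That call ended in 5 of the alternative settings planned in advance, with adjusted p from 0.0508 to 0.190. PTGDR2 stood at 4.55 ± 3.28 against 1.94 ± 1.95 CPM and did not pass (edgeR adjusted p = 0.141). Other increases were C12orf33 (log2 fold change 1.14, SE 0.23), CG030 (1.91-fold), PTCH1, the Hedgehog receptor gene (1.88-fold), and CHRNB1 (1.79-fold). KLRG1, a receptor of differentiated T cells, rose by 0.76 (SE 0.19), and the transcription factor gene IRF1 by 0.52 (SE 0.13). Other decreases were H1FX, a linker histone gene (2.23-fold), the monocarboxylate transporter gene SLC16A6 (2.18-fold), TMEM119 (2.14-fold), RRM2 (2.11-fold), MTA1 (2.10-fold) and ZNRF1 (2.10-fold). CD3E, a gate marker, fell by 0.28 (SE 0.07), a call that ended without scaling factors (adjusted p = 0.0604). MKI67, a proliferation marker, PDCD1, KLF2, PIM3, PFKFB3, SLC16A3 and BHLHE40 also fell. The calls of BCL3, BHLHE40, CD83, CG030, IRF1, KLRG1, MKI67, PTCH1, SLC16A3, TNFAIP3, TSC22D3 and ZNRF1 each ended in at least 1 alternative setting. With each library's immediate early score as a covariate, 22 of the 37 named genes past the threshold in rhinitis kept their calls.

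The Th17 and Th22, cell cycle, follicular helper, histone and chemokine receptor lists were called lower in rhinitis and the interferon gamma list higher. Members past the threshold were 0 of 12, 2 of 19, 1 of 11, 0 of 11, 0 of 25 and 1 of 15 in that order. These 6 camera calls (adjusted p from 6.1e-04 to 0.0496) were lost with an estimated correlation (adjusted p from 0.197 to 0.394), and the other 29 lists were not called (camera adjusted p from 0.0637 to 1.00). The marker share of Th17 and Th22 genes was lower in rhinitis by 0.33 on the log2 scale (adjusted p = 0.0424, permutation test), with 1072 ± 237 CPM against 1342 ± 282 CPM, a call that ended on the linear scale (adjusted p = 0.0571). The count of genes was sensitive to single libraries: 117 genes passed without 1 healthy library, 138 without another and 145 without a rhinitis library. It was 86 when the asthma libraries were left out of the fit, 130 with the number of detected genes as a covariate, 639 with 2 surrogate variables and 722 with limma voom.

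**Figure D2:**
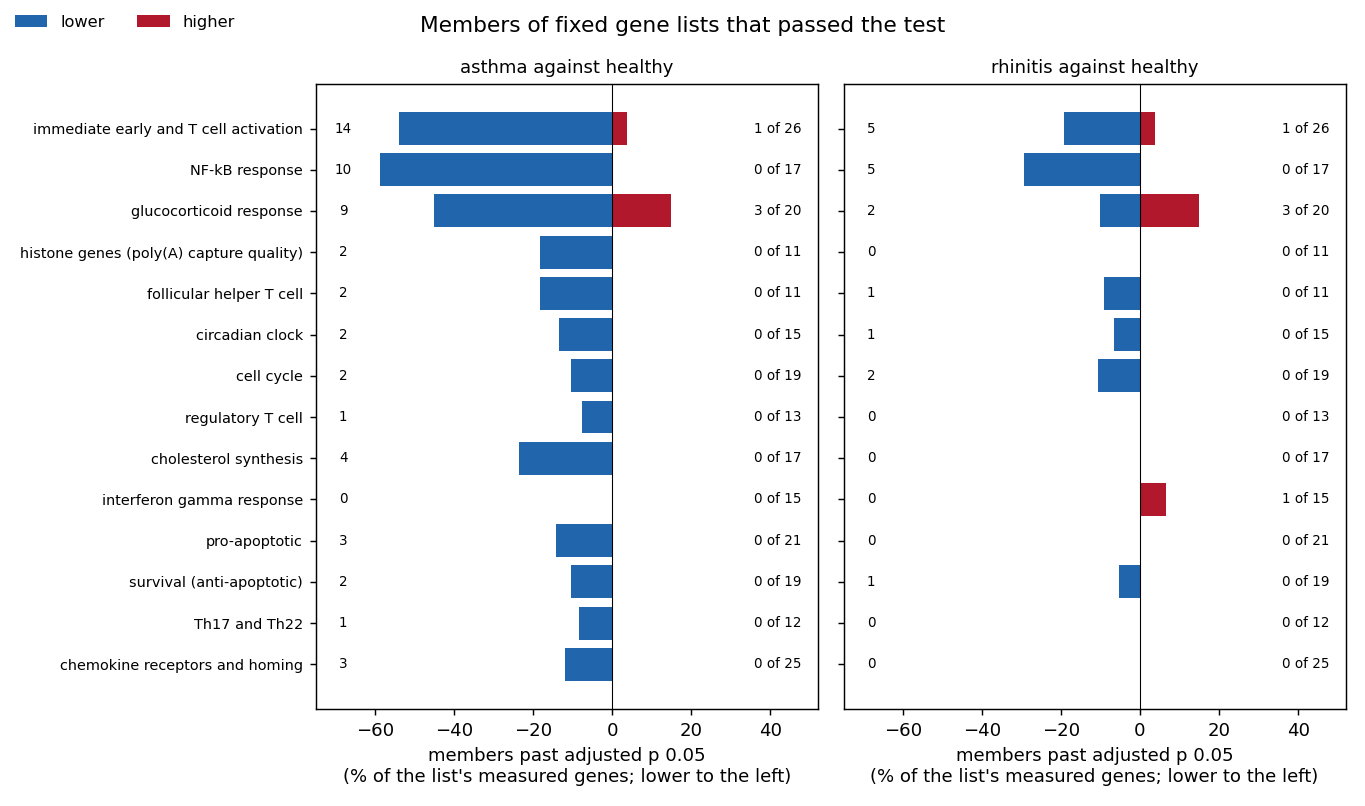
Members past adjusted p 0.05 in the fixed gene lists called in asthma or in rhinitis, as percent of each list's measured genes (horizontal axes, lower to the left in blue and higher to the right in red), with the numbers of lower and higher members printed. The immediate early list had 14 of 26 genes lower in asthma and 5 of 26 in rhinitis, and the NF-kB list 10 of 17 and 5 of 17.

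Both allergic groups were compared with the same 15 healthy libraries. Of the genes that passed, 51 were higher and 79 lower in both comparisons, 130 in all. Independent lists would share 1.13 and 2.78, but comparisons with shared controls are not independent, so these numbers are no baseline here. Over all tested genes 74.5% had the same sign in both comparisons, against 73.8% on average in simulations with no group effect. The highest of 20 simulations had 74.8%, so the share of same signs was not beyond the range with no group effect. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated with r = 0.766, against 0.679 in simulations with no group effect and shared controls. The covariance was 0.0506 against 0.0211 simulated, a difference of 0.0295. With the healthy libraries split into 8 and 7, the covariance averaged 0.0293, r averaged 0.288 and 11.9 genes were shared on average, from 155 and 34.9 genes past the threshold.

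**Figure D3:**
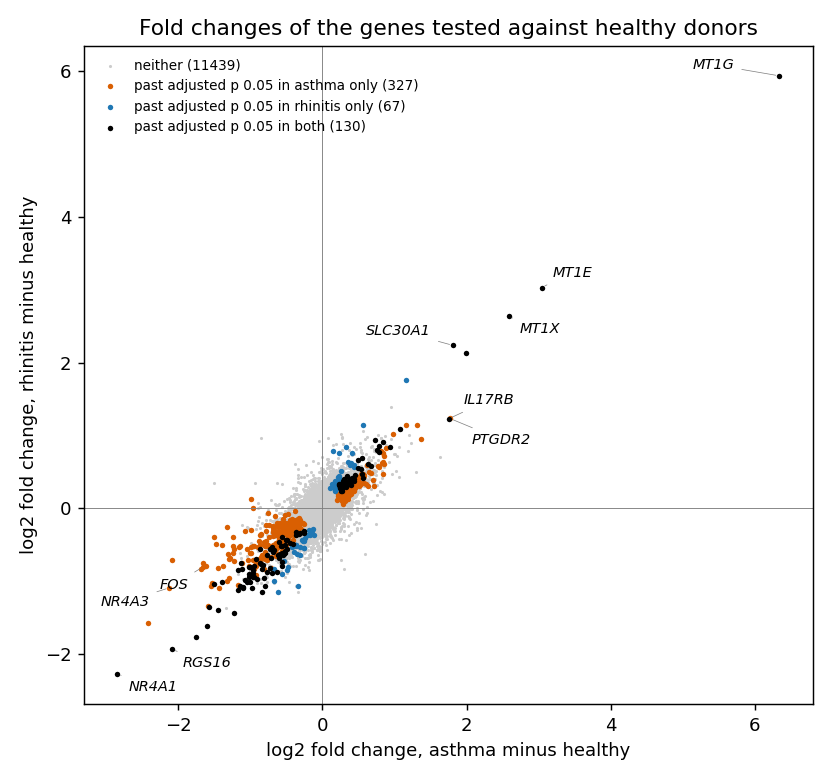
Log2 fold change of each of 11963 genes in asthma (horizontal axis) and in rhinitis (vertical axis), each against the same 15 healthy libraries, coloured by the comparisons in which the gene passed adjusted p 0.05. The 130 genes past the threshold in both lie along the diagonal, with NR4A1 and RGS16 at the lower end and MT1G, MT1E, MT1X, MT2A and SLC30A1 at the upper end.

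The third comparison set asthma against rhinitis. A single gene passed, DUSP8, a MAP kinase phosphatase gene, which was 2.44-fold lower in asthma at 1.71 ± 1.08 CPM (SD, n = 40) against 4.23 ± 4.81 CPM (SD, n = 25), with an adjusted p of 0.0495 in edgeR. At an unadjusted p under 0.05 there were 1468 genes, where 598 are the chance number. Because genes vary together, this excess alone does not show a group difference. Across genes the log2 fold changes of this comparison rose with GC content (Spearman rho = 0.185) and fell with length (rho = −0.161). In asthma against healthy these rho were 0.036 and −0.12, and in rhinitis against healthy −0.104 and 0.008. The cause of these trends was not tested. GABARAPL1, an autophagy gene, was next by p, with a log2 fold change of −1.12 (SE 0.24, adjusted p = 0.0888 in edgeR) and 21 of 40 asthma libraries below the rhinitis median, and it was past the threshold in place of DUSP8 in DESeq2 (adjusted p = 0.0204). DUSP10, FOXJ2, ELL2, PELI1, PIK3C2A, ZNF540, AFF4 and IDI2-AS1 followed with edgeR adjusted p of 0.137 and lower means in asthma. PTGDR2 and IL17RB did not pass, with log2 differences of 0.54 (SE 0.31, adjusted p = 0.476) and 0.53 (SE 0.25, adjusted p = 0.380) in edgeR. The immediate early, NF-kB, glucocorticoid and heat shock lists were called lower in asthma by camera (adjusted p = 1.2e-04, 0.0213, 0.0213 and 0.0394), although none of their members passed. When adjusted over the list alone, 10 fell and 1 rose of the 26 immediate early genes, 2 of the 17 NF-kB genes fell, 5 of the 20 glucocorticoid genes fell and 2 of the 13 heat shock genes fell. All 4 calls were lost with an estimated correlation (adjusted p = 0.550), and the other 34 lists were not called (camera adjusted p from 0.0598 to 0.951). None of the 14 marker shares differed in the permutation test. The DUSP8 call ended in 7 of the 14 alternative settings that gave it an adjusted p, among them limma voom, in which no gene passed. Leaving out single libraries gave between 0 and 3 genes.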

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

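The explanations of the immediate early pattern were tested only after that pattern was seen, and the counts over other splits of the libraries were read after the gene counts. Asthma and rhinitis were each set against healthy donors, and 5 results differed between the 2 allergic groups by the direct test of that difference. DUSP8 was lower in asthma than in rhinitis by edgeR's quasi-likelihood test (log2 fold change −1.29, SE 0.26, adjusted p = 0.0495, below the rhinitis median in 31 of 40 asthma libraries). The immediate early and T cell activation list (camera adjusted p = 1.2e-04), the NF-kB response list (0.0213), the glucocorticoid response list (0.0213) and the heat shock list (0.0394) were lower in asthma than in rhinitis. None of the 4 list calls held with an estimated correlation (adjusted p = 0.550), and none of their members passed alone. Of 100 splits of the asthma and rhinitis libraries into groups of the same sizes, 7 gave at least 1 gene, the real one included, and the highest other count was 5 genes, so chance cannot be excluded for the single gene.

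The lower immediate early and NF-kB genes in asthma than in healthy donors were weighed against 3 technical explanations. Depth alone is argued against: of 24 list members that were lower, 23 stayed past the threshold with log2 library size as a covariate. Fewer monocytes in the asthma libraries are argued against too, because their marker share was 0.0747 higher on the log2 scale (95% bootstrap interval −0.388 to 0.540) where the list members fell by a median of 0.98, with LYZ at 54.2 against 46.8 CPM and S100A9 at 23.4 against 22.4 CPM, and the CD3 gate would remove such cells. Handling of blood before the sort, which can induce these genes within the time of a preparation, may have differed between donor groups and cannot be told apart from disease here, since no batch is given, and disease stays open and untested. With the immediate early score as a covariate 14 of the 457 genes remained past the threshold, but that score is the mean of immediate early list genes, so this count does not tell handling from disease, and why the calls of genes outside the list ended was not tested (PTGDR2 fell from 1.77 to 0.70, while MT1X at 2.58 and 2.72 and SLC30A1 at 1.81 and 1.84 kept the size of their changes).

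Chance is argued against for the count in asthma against healthy: of 100 splits, 1, the real one, gave 457 genes, and the highest other gave 23. A share below 1 of 100 cannot be seen with this number of splits. For rhinitis against healthy 2 of 100 splits, the real one included, gave at least the real 197 genes, a share under 0.05. The highest other split gave 328 genes, more than the real one, and 18 splits besides the real one gave at least 1 gene. The count of 197 is thus not beyond the range of the splits, and chance cannot be fully excluded for it.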

How the results depend on the processing

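All gene counts come from edgeR with one choice changed at a time unless another tool is named. The settings that left out single libraries or those apart on principal components, or that used the GC and length offset or the immediate early score, were chosen after seeing the data. For asthma against healthy the 457 genes stayed within 1.5 times in the settings tried except 4: 697 with only the 2 groups in the fit (452 of the 457 shared), 208 at a fold of at least 1.5, 1735 with limma voom (443 shared) and 20 with the immediate early score (14 shared). Leaving out single libraries gave 314 to 656 genes, and leaving out those apart on principal components 671. For rhinitis against healthy the 197 genes became 86 with only 2 groups in the fit, 130 with detected genes as a covariate, 639 with 2 surrogate variables, 94 at a fold of at least 1.5 and 722 with limma voom. Leaving out single libraries gave 117 to 277, the lowest without 1 healthy library, and the GC and length offset gave 218 genes, 43.1% of them lower against 55.8%. The immediate early score gave 212 genes in rhinitis, 29.7% of them lower, with 95 of the 197 shared. For asthma against rhinitis the single gene became 0 with upper-quartile scaling, no scaling, the stricter filter, 2 groups in the fit, 2 surrogate variables, limma voom, the immediate early score or without the libraries apart on principal components. It became 2 with non-robust estimates or log2 library size as a covariate, 3 without the libraries apart in depth and 22 without a filter, DESeq2 also gave 1 gene but another one, and leaving out single libraries gave 0 to 3, most often 0, with 1468 genes at an unadjusted p under 0.05 with all libraries. With an estimated correlation the called lists went from 12 to 2 in asthma, from 9 to 0 in rhinitis and from 4 to 0 between them, while fry called 15, 6 and 0 lists. The 4 and 1 marker shares called became 0 on the linear scale and 0 without the libraries apart in depth, although without those libraries the log2 differences stayed similar (B cell 0.34 from 0.32, follicular helper −0.26 from −0.25, Th2 lineage −0.14 from −0.15 and Th17 and Th22 −0.22 from −0.26 in asthma, and Th17 and Th22 −0.30 from −0.33 in rhinitis). The difference in detected genes between asthma and rhinitis, −27.1 and not past the threshold, reversed to 128 when detection required 10 counts, and that between rhinitis and healthy went from 235 to 96.6.

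Of the 802 values of called named genes in asthma under planned settings, 777 kept direction and threshold and 25 fell short of it, and in rhinitis 444 of 480 did and 36 fell short. With the immediate early score, added later, 1 of 62 such genes in asthma, MT1G, kept its call, 55 kept the direction without the call (some, as MT1X at 2.58 and 2.72, with changes as large) and 6 reversed, and in rhinitis 22 of 37 kept the call and 15 the direction without it. With the immediate early score as a covariate, which is the mean of immediate early list genes, FOS, NR4A2 and NR4A3 among them, CXCR4 (0.017), FOS (0.30), NAMPT (0.088), NR4A2 (0.12), NR4A3 (0.10) and SLC2A3 (0.12) reversed in asthma, GATA3 (0.029) in rhinitis and CCR4 (0.026) between the allergic groups. With 2 surrogate variables RORC (−0.072) reversed in asthma, and CCR4 (0.057) and TBX21 (−0.022) between the allergic groups. In that comparison CCR4 (0.067) and FOXP3 (−0.014) reversed with limma voom, and TBX21 without the libraries apart in depth (−0.024) and with the GC and length offset (−0.045). None of these log2 values passed the threshold, and the cause was not tested. Genes under about 1 CPM, such as IL4, IL5 and IL13, are limited by depth.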

Other observations

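The tests on metallothioneins and of the immediate early axis were chosen after the results were seen, and the test on genes that follow PTGDR2 was fixed before its result was seen. HMGB2, ODC1 and SLC16A6 had the 3 smallest p-values in both comparisons with healthy donors, and THAP1 the next in rhinitis. The naming rule reached only SLC16A6 in rhinitis, and the others were chosen after their values were seen. HMGB2, a chromatin protein gene, was at 261 ± 62.8 CPM in asthma (SD, n = 40), 265 ± 45.3 CPM in rhinitis (SD, n = 25) and 510 ± 137 CPM in healthy donors (SD, n = 15). It lay below the healthy median in 40 of 40 asthma and 25 of 25 rhinitis libraries (log2 fold change −0.97, SE 0.09, edgeR adjusted p = 1.1e-13 in asthma). ODC1, the rate-limiting enzyme of polyamine synthesis, was at 153 ± 44.4, 156 ± 40.8 and 316 ± 96.4 CPM, and SLC16A6, a monocarboxylate transporter gene, at 12.7 ± 4.53, 13.2 ± 4.51 and 28.6 ± 10.7 CPM in the same order. Both also lay below the healthy median in 40 of 40 and 25 of 25 libraries. THAP1, a zinc finger transcription factor gene, was higher, at 32.8 ± 6.25, 36.4 ± 7.84 and 22.5 ± 4.47 CPM. Both comparisons used the same 15 healthy libraries, so they are not independent results for these genes. Handling that differed for the healthy libraries cannot be told apart from disease here, since no batch is given. With the immediate early score as a covariate the changes of these genes in asthma were smaller. HMGB2 went from −0.97 to −0.89 (SE 0.10, edgeR adjusted p = 2.9e-09) and ODC1 from −1.05 (SE 0.12) to −0.74 (SE 0.12, adjusted p = 3.0e-04), both still past the threshold. SLC16A6 went from −1.17 (SE 0.14) to −0.95 (SE 0.16, edgeR adjusted p = 3.9e-04) and also stayed past it. THAP1 went from 0.55 (SE 0.09) to 0.41 (SE 0.10) in asthma, no longer past the threshold (edgeR adjusted p = 0.0627). In rhinitis THAP1 went from 0.70 (SE 0.10) to 0.61 (SE 0.10) and kept its call (edgeR adjusted p = 1.5e-04).

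Of 6 tested metallothionein genes, grouped after their values were seen, 5 passed as higher in asthma and 4 in rhinitis (MT1G, MT1E, MT1X and MT2A in both), as did SLC30A1 in both, and 3 explanations were tested. That only a few libraries were higher is argued against: the mean log2 CPM of 6 metallothionein genes exceeded the highest healthy library in 30 of 65 allergic libraries (18 of 40 asthma, 12 of 25 rhinitis). If all groups were alike 4.06 would do so, but the genes were grouped after their increase was seen, so that number is no fair baseline. The count does not show how much of the mean change a few libraries carried. With limma voom and sample quality weights the changes were smaller and their calls ended. A glucocorticoid response that raised the whole list is argued against, because the 17 other genes of that list had a median log2 fold change of −0.599 (MAD 0.43) in asthma and −0.50 (MAD 0.33) in rhinitis, where the metallothioneins had 2.29 and 2.38. Those genes include DUSP1, also an immediate early gene, and CXCR4, which reversed in asthma with the immediate early score. Their median therefore cannot exclude a glucocorticoid part beneath the immediate early decrease. By permutation tests no relation of FKBP5 with the metallothionein score was detected within asthma (r = 0.0453, p = 0.781) or rhinitis (r = 0.15, p = 0.474). A metal response is a candidate explanation that the tests leave standing: within rhinitis SLC30A1 followed the metallothionein score with r = 0.912 (rho = 0.861, n = 25, r = 0.853 without the 2 farthest libraries), and within asthma with r = 0.836 (rho = 0.833, n = 40, r = 0.768 without them), each with a permutation p of 1e-05, the smallest the resamples can give (adjusted p = 6e-05 over 12 relations), while in healthy donors r was −0.283 (p = 0.311, rho = −0.168, p = 0.552, permutation tests, n = 15, r = 0.0112 without them). Whether such a response arose in the donors or in the handling of the samples stays open, because no batch is given.

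PTGDR2 and IL17RB were higher in asthma, and a larger share of cells expressing both in the sorted gate is a candidate explanation. By permutation tests over 12 relations the 2 genes correlated within asthma (r = 0.456, p = 0.0033, adjusted p = 0.0079, rho = 0.431, p = 0.0062, n = 40, r = 0.542 without the 2 farthest libraries) and within rhinitis (r = 0.463, p = 0.0206, adjusted p = 0.0412, rho = 0.494, p = 0.0129, n = 25, r = 0.548 without them), with no correlation detected in healthy donors (r = 0.0343, p = 0.902, rho = 0.161, p = 0.565, n = 15, r = 0.35 without them). The 50 genes that followed them most closely within asthma had a median log2 fold change of 0.0568 in rhinitis against healthy, at the 92.8 percentile of 10000 random lists of matched expression, below the bound set in advance, so the test does not decide. With the immediate early score as a covariate 0 of the 2 genes passed, PTGDR2 going from 1.77 (SE 0.42) to 0.70 (SE 0.44) and IL17RB from 1.76 (SE 0.34) to 1.23 (SE 0.36, adjusted p = 0.141), so PTGDR2 lost more of its change than IL17RB and the test leaves the part of that axis open. In the same permutation tests PTGDR2 fell with that score within asthma (r = −0.497, p = 0.0014, adjusted p = 0.0056, rho = −0.507, p = 0.0011, n = 40, r = −0.414 without the 2 farthest libraries) and within rhinitis (r = −0.57, p = 0.0028, adjusted p = 0.0079, rho = −0.682, p = 3.7e-04, n = 25, r = −0.518 without them), but no such relation was detected in healthy donors (r = −0.111, p = 0.697, rho = 0.10, p = 0.723, n = 15, r = 0.51 without them).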
